A study of Rattus norvegicus with 6 samples.

How the data were processed

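Primary astrocytes from rat brain were either left as controls or treated with β-hydroxybutyrate (BHB), the main ketone body in blood during fasting or a ketogenic diet. Per the labels' protocols, RNA was extracted with a column kit, poly(A) RNA was captured on oligo-dT beads, and libraries were made with the Illumina TruSeq RNA kit, version 2 (v2). There were 3 control and 3 BHB libraries, grouped by their treatment labels. The column names of the deposited table give the BHB dose as 2 mM. The duration of treatment is not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

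The authors deposited a single table of FPKM values (fragments normalised to transcript length and to the mapped fragments of the library), with 22608 gene symbols and a column for each of the 6 libraries. The submitters' processing notes name bcl2fastq 2.0, HISAT2 and StringTie among the tools and rn6 as the genome build, without their roles, order or settings. The annotation, the strand setting and the treatment of reads shared between near-identical genes are not given in the sources used here. FPKM is divided by gene length and library depth, so it cannot be tested as read counts, and the depth of each library is unknown. Among genes under 0.1 FPKM, the most frequent ratio of values between libraries estimates what 1 read is worth. Relative to control 1 it lay between 0.850 (control 3) and 1.01 (BHB 2), so the depths inferred in this way differed little.

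The deposited values differ in their number of decimals. Of the 12373 genes tested, 5267 had at most 6 decimals in all libraries and 7106 (57.4%) had more. A RefSeq gene table of a later assembly (GRCr8), used only for symbols, identifiers and transcript numbers, matched 17144 of the 22608 symbols and 10938 of the tested ones. Matched genes with at most 6 decimals had a median of 2 listed transcripts, and those with more had a median of 5. Genes with a single listed transcript made up 46.9% of the former and 5.94% of the latter. How a gene's value was combined from its transcripts is not given in the sources used here. No coordinates are given, since the builds differ.

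Values were transformed as log2(FPKM + 1) with no further scaling. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested. The treatment effect was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All adjusted p-values of genes come from this fit. Log2 fold changes (BHB over control) are on the log2(FPKM + 1) scale. This scale understates changes, most in genes near or under 1 FPKM and to a lesser degree in genes of a few FPKM. Ratios are of mean FPKM. Intervals are 95% confidence intervals from the same fit. For the glutamate transporter genes and Glul an exact two-sided permutation test of the group means was also run, whose smallest possible p with 3 against 3 is 0.1.

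Gene lists for astrocyte functions, metabolism, stress and inflammatory responses, and brain cell types were fixed before the data were examined, as were the design, the named genes and most alternatives. There were 33 lists holding 635 symbols, of which 1 (Iigp1) was not found in the table. In 4 lists a gene had been entered under an older and a newer name, and 9 such duplicates were merged into a single entry. The 31 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The number of members passing is given over all genes tested and adjusted over the list alone.

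Genes were named by rule. Slc1a1, Slc1a2, Slc1a3 and Glul were always named. Up to 10 genes per direction were named among those passing the test with a mean of at least 2 FPKM in the higher group and groups that did not overlap. Up to 4 members with the smallest p were named for each list described, with the most abundant member of cell type lists and the 5 most abundant genes overall. Some genes that the rule selects are not reported here. Members named outside this rule are said to have been chosen after their values were seen.

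Data were simulated as normal noise around the means of the 12373 genes, with spreads as shrunk by eBayes and no jumps of single libraries. The fit was tested on such data in 20 simulations with 50 changed genes per size. For BHB against control it recovered 18.4% of changes of 0.25 on the log2 scale, 83.9% at 0.5, 98.9% at 1 and 99.9% at 1.5, and 5.96% of calls were false. A list of 18 genes shifted by 0.2 was found in 20 of 20 simulations, and 1 of 600 unshifted lists was called. These genes were simulated as independent, so the list result does not cover correlated genes. The 20 simulations gave 3224 calls in all, far more per simulation than the 7 in the data. The adjustment is less strict where more genes change, so recovery in the data may be lower than these shares.

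The alternatives were other pseudocounts (0.1 and 0.5), no filter or a minimum of 5 FPKM, 3 scalings, other eBayes and weight settings, stricter thresholds, other list tests, the replicate number as a block, and leaving out each library in turn. Restricting the test to genes with at most 6 decimals, leaving out genes with 2 tight levels, and leaving Fos and Fosb out of their list were added after seeing the data. Searches for genes with 2 tight levels and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.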

Results

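Poly(A) RNA sequencing compared 3 libraries of control and 3 of BHB-treated rat primary astrocytes. Each library had between 12288 and 12312 genes at 1 FPKM or more, and the sums of FPKM ran from 354565 to 367448. The most abundant genes were the cytoskeletal and actin-binding genes Tmsb4x, Vim, Actb and Tagln and the astrocyte phosphoprotein gene Pea15, which together held 4.68% to 4.92% of the summed FPKM. Astrocyte genes were strongly expressed in controls. Fabp7, a fatty acid binding protein of radial glia and astrocytes, stood at 2319 ± 90.2 FPKM and the intermediate filament gene Gfap at 1438 ± 59.5 FPKM (SD, n = 3 each). Libraries were alike, with pairwise Pearson correlations over the tested genes of 0.990 to 0.993. The mean correlation was 0.992 within groups and 0.992 between groups.

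The series asks how BHB acts on glutamate uptake and its transporters in astrocytes. Slc1a3, which encodes the glial glutamate transporter GLAST, was higher with BHB, at 202.7 ± 5.0 FPKM in controls and 455.2 ± 11.6 FPKM with BHB (SD, n = 3 each). The ratio was 2.25, and the log2 fold change of 1.16 (SE 0.0400) had an adjusted p of 1.64e-05 in limma. All 3 BHB libraries, at 445.4 to 468.0 FPKM, lay above all 3 controls, at 197.0 to 206.4 FPKM. Slc1a2, which encodes GLT-1, the other main astrocyte transporter, was far less abundant and differed by less than the spread between libraries. It stood at 5.83 ± 0.0836 FPKM in controls and 6.06 ± 0.496 FPKM with BHB (SD, n = 3 each), with a log2 fold change of 0.05 (95% interval -0.12 to 0.21, limma adjusted p = 0.943). Slc1a1, the transporter EAAC1, stood at 4.87 ± 0.694 and 4.94 ± 0.244 FPKM (SD, n = 3 each), a log2 fold change of 0.02 (95% interval -0.19 to 0.24, limma adjusted p = 0.980).

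Glul, the glutamine synthetase that converts glutamate to glutamine in astrocytes, stood at 245.0 ± 3.26 FPKM in controls and 258.0 ± 10.1 FPKM with BHB (SD, n = 3 each). Its log2 fold change of 0.07 (95% interval -0.02 to 0.17) did not pass (limma adjusted p = 0.890). The exact two-sided permutation p was 0.1 for Slc1a3 and Glul, 0.4 for Slc1a2 and 0.8 for Slc1a1, and 0.1 is the smallest that 3 against 3 allows. The direction of Slc1a1 turned without control 3 (log2 fold change -0.05) and without BHB 2 (-0.01). The values of Slc1a3 have more than 6 decimals, and among genes of at least 10 FPKM 100 others took 2 tight levels at least 1.5-fold apart in groupings of the libraries that did not follow treatment. Of these, 62 set 1 library apart, where that level is tight by definition, and 32 set 2 apart. The remaining 6 fell in the 9 other splits into 3 and 3, and 1 of these genes was at least 2-fold.

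**Figure D1:**
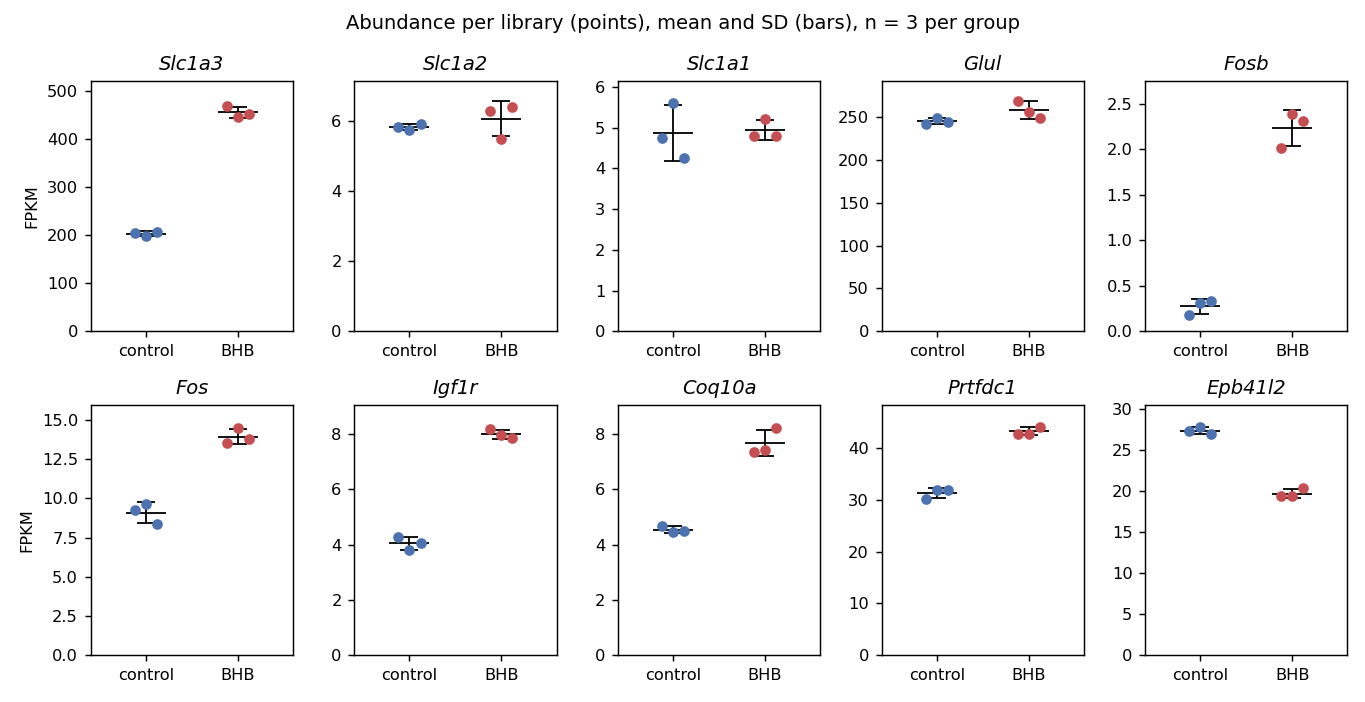
FPKM of 10 genes in each library (points, control in blue and BHB in red), with the mean and SD of 3 libraries per group (bars) on linear axes from 0. Slc1a3 lies at 197.0 to 206.4 FPKM in controls and 445.4 to 468.0 FPKM with BHB, while the groups overlap for Slc1a2 and Slc1a1.

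Across the 12373 genes tested, 7 passed, 6 higher and 1 lower with BHB. Besides Slc1a3, the higher genes were Fosb and Fos, subunits of the AP-1 transcription factor, Igf1r, the receptor of insulin-like growth factor 1, Coq10a, a coenzyme Q binding protein of mitochondria, and Prtfdc1, a relative of the purine salvage enzyme HPRT. Fosb rose from 0.276 ± 0.0840 to 2.24 ± 0.197 FPKM (SD, n = 3 each), a log2 fold change of 1.34 with a limma adjusted p of 0.00258, and its low control level makes the fold change depend on the pseudocount (2.66 with 0.1). Fos rose from 9.10 ± 0.668 to 13.9 ± 0.487 FPKM (SD, n = 3 each; log2 fold change 0.57, limma adjusted p = 0.0402). Igf1r rose from 4.05 ± 0.239 to 8.0 ± 0.164 FPKM (SD, n = 3 each; log2 fold change 0.84, limma adjusted p = 0.00434). Coq10a rose by 0.64 and Prtfdc1 by 0.45 on the log2 scale, and Epb41l2, a membrane skeleton protein of the 4.1 family, had a log2 fold change of -0.46 (limma adjusted p = 0.0198 for each). In each of these 7 genes the groups did not overlap.

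At an unadjusted p under 0.05 there were 692 genes, 427 higher and 265 lower, or 5.59% of those tested. The groups did not overlap in 1347 genes, or 10.9%, where chance gives 10%. A difference of at least 2-fold on the log2(FPKM + 1) scale was seen in 12 genes, of which Slc1a3 and Fosb passed. The calls of Coq10a, Fos and Epb41l2 ended when any library was left out (limma adjusted p 0.0546 to 0.175), and that of Prtfdc1 ended without any library except control 3 (highest 0.0819). Without the FPKM minimum Coq10a and Fos did not pass, and without the eBayes trend Fos, Prtfdc1 and Epb41l2 did not.

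Immediate early genes, which respond within minutes to growth factors, calcium and stress, were higher as a list with camera's preset correlation. Camera gave an adjusted p of 4.42e-14, and an adjusted p of 0.240 with an estimated correlation. Fry, which tests whether the members move one way on balance, gave an adjusted p of 0.0240. Of 18 tested members 17 had a log2 fold change above 0, with a median of 0.20. Fosb and Fos passed over all genes tested, and 9 were higher adjusted over the list alone. These included the nuclear receptor gene Nr4a1, from 0.610 to 1.29 FPKM (log2 fold change 0.50), and the AP-1 gene Junb, from 25.5 to 32.0 FPKM (0.32). With a pseudocount of 0.1 the log2 fold change of Nr4a1 was 0.96. The other 5, named here after their values were seen, were Dusp1, Ier3, Egr1, Btg2 and Ier2, with log2 fold changes of 0.33, 0.18, 0.41, 0.19 and 0.19.

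Genes of the NF-kB and inflammasome list, which covers cytokines, chemokines and feedback inhibitors of NF-kB, were also higher as a list with the preset correlation. The camera adjusted p was 1.12e-04, and the adjusted p was 0.405 with an estimated correlation and 0.139 with fry. Of 16 tested members 13 lay above 0, with a median log2 fold change of 0.19. None passed over all genes tested in limma, while 9 had an unadjusted p under 0.05 and, adjusted over the list alone, 7 were higher and 1 lower. The chemokine genes Ccl2 (23.7 to 31.3 FPKM) and Ccl7 (3.93 to 5.10 FPKM) had log2 fold changes of 0.39 and 0.30. Tnfaip3, an inhibitor of NF-kB signalling, and Nfkb1, an NF-kB subunit, had 0.36 and 0.21, and Tnfaip3 had 0.55 with a pseudocount of 0.1. Also higher, named after their values were seen, were Nfkbiz, Cxcl1 and Nfkbia, and the lower member was the cytokine gene Il18, at 3.28 FPKM in controls and 2.40 FPKM with BHB (-0.33). Nlrp3, Il1b, Tnf and Il6, also named after their values were seen, had means under 1 FPKM in both groups and were not tested.

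**Figure D2:**
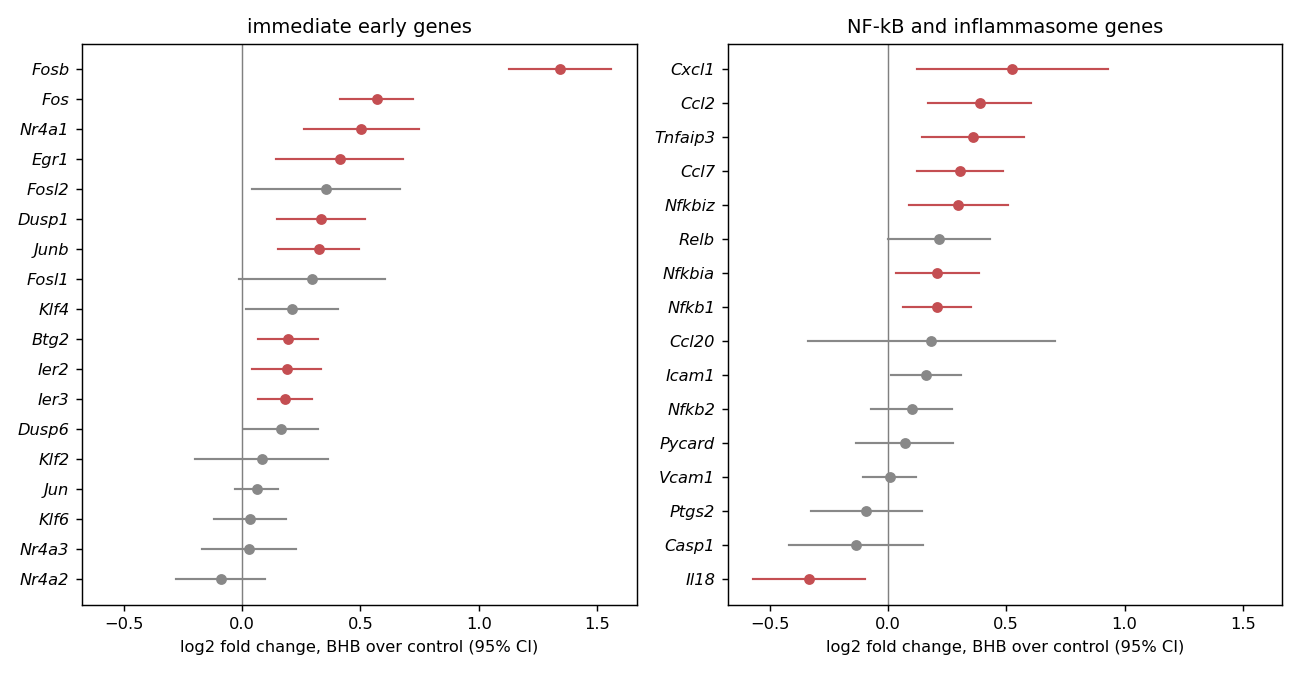
Log2 fold change (BHB over control) of the tested immediate early genes (left, 18 genes) and NF-kB and inflammasome genes (right, 16 genes), each with its 95% confidence interval. Members that pass adjusted over the list alone are red and the others grey, and Fosb lies farthest right at 1.34.

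Markers of reactive astrocytes showed small shifts. Of 12 tested pan-reactive markers 11 lay above 0, with a median log2 fold change of 0.09 (camera adjusted p = 0.00317, adjusted p = 0.443 with an estimated correlation). None passed over all genes tested in limma, 1 had an unadjusted p under 0.05, and adjusted over the list alone only S1pr3, a sphingosine 1-phosphate receptor, was higher, at 62.6 and 71.8 FPKM. Of 10 tested A2 markers, a set described after ischaemia, 8 lay above 0, with a median of 0.09 (camera adjusted p = 0.0136, adjusted p = 0.405 with an estimated correlation). None passed over all genes tested, 3 had an unadjusted p under 0.05, and adjusted over the list alone the transcription factor gene Stat3 (0.19) and the pentraxin gene Ptx3 (0.35) were higher. Of 10 tested A1 markers, a set described after inflammatory stimulation, 5 lay above and 5 below 0, and the list was not called (camera adjusted p = 0.938). The pan-reactive call ended without BHB 3 (adjusted p = 0.0894), and the A2 call ended without control 2 (0.123), without BHB 1 (0.0768) and on ranks (0.0614).

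Glycolysis genes were called higher as a list by a small margin. Of 20 tested members 17 lay above 0, with a median log2 fold change of 0.06 (camera adjusted p = 0.00921, adjusted p = 0.916 with an estimated correlation). No member passed over all genes tested or adjusted over the list alone in limma, and 1 had an unadjusted p under 0.05. The pyruvate kinase gene Pkm stood at 178.3 and 193.8 FPKM and the lactate dehydrogenase gene Ldha at 231.6 and 246.5 FPKM in controls and BHB. The call ended without control 1 (adjusted p = 0.0537), control 3 (0.201), BHB 2 (0.161) or BHB 3 (0.0568), and under quantile normalization (0.0730).

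Genes that handle ketone bodies and monocarboxylates were not called as a list. Of 12 tested members 9 lay above 0, with a median log2 fold change of 0.03 (camera adjusted p = 0.773), and none passed. Acat1, which splits acetoacetyl-CoA, stood at 25.4 and 27.2 FPKM in controls and BHB. Genes of glutamate and glutamine metabolism did not pass either (18 tested, 11 above 0, camera adjusted p = 0.871), nor did glutamate receptors (9 tested, 6 above 0, camera adjusted p = 0.938). The kinases of the CaMK and AMPK families (15 tested, 7 above 0, camera adjusted p = 0.938) included Camkk2, a kinase that activates AMPK, at 2.16 ± 0.334 and 3.11 ± 0.459 FPKM (SD, n = 3 each), a log2 fold change of 0.38 that did not pass (limma adjusted p = 0.881). Histone deacetylases and sirtuins (18 tested, 9 above 0) and oxidative stress genes linked to deacetylase inhibition (15 tested, 9 above 0) were not called (camera adjusted p = 0.938 for each).

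Astrocyte markers other than Slc1a3 lay close to 0, with a median log2 fold change of -0.02 over these 20 (SD 0.0725). Of the 21 tested with Slc1a3 included, 10 lay above 0, and only Slc1a3 passed. The median over the 21 was -0.01 and the mean 0.06, which differ in sign, and the list was not called (camera adjusted p = 0.809). Fry called it (adjusted p = 0.0240), with Slc1a3 among its members. Among markers of other cell types, microglia genes (16 tested, 6 above 0, camera adjusted p = 0.871) were not called, nor were fibroblast and mural cell genes (11 tested, 7 above 0, camera adjusted p = 0.938), which reached 3030 FPKM in controls for Tagln. Oligodendrocyte lineage genes (10 tested, 6 above 0, highest Cnp) and ependymal genes (5 tested, 2 above 0, highest Foxj1) were not called either (camera adjusted p = 0.938 for each). Neuron markers had 10 of 12 tested members below 0 and a median of -0.05, and were not called (camera adjusted p = 0.0523), but were called lower without control 2 (0.0414) or without BHB 3 (0.0218). Median, mean and test differed in sign in 11 of the 31 lists tested, none of them called. Besides the astrocyte markers, these were the CaMK and AMPK kinases, glutamate metabolism, glutamate receptors, fibroblast, oligodendrocyte and ependymal markers, fatty acid synthesis, the heat shock and hypoxia responses and the tricarboxylic acid cycle. Of the endothelial markers 1 reached the minimum, Eng, at 2.25 and 2.44 FPKM.

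**Figure D3:**
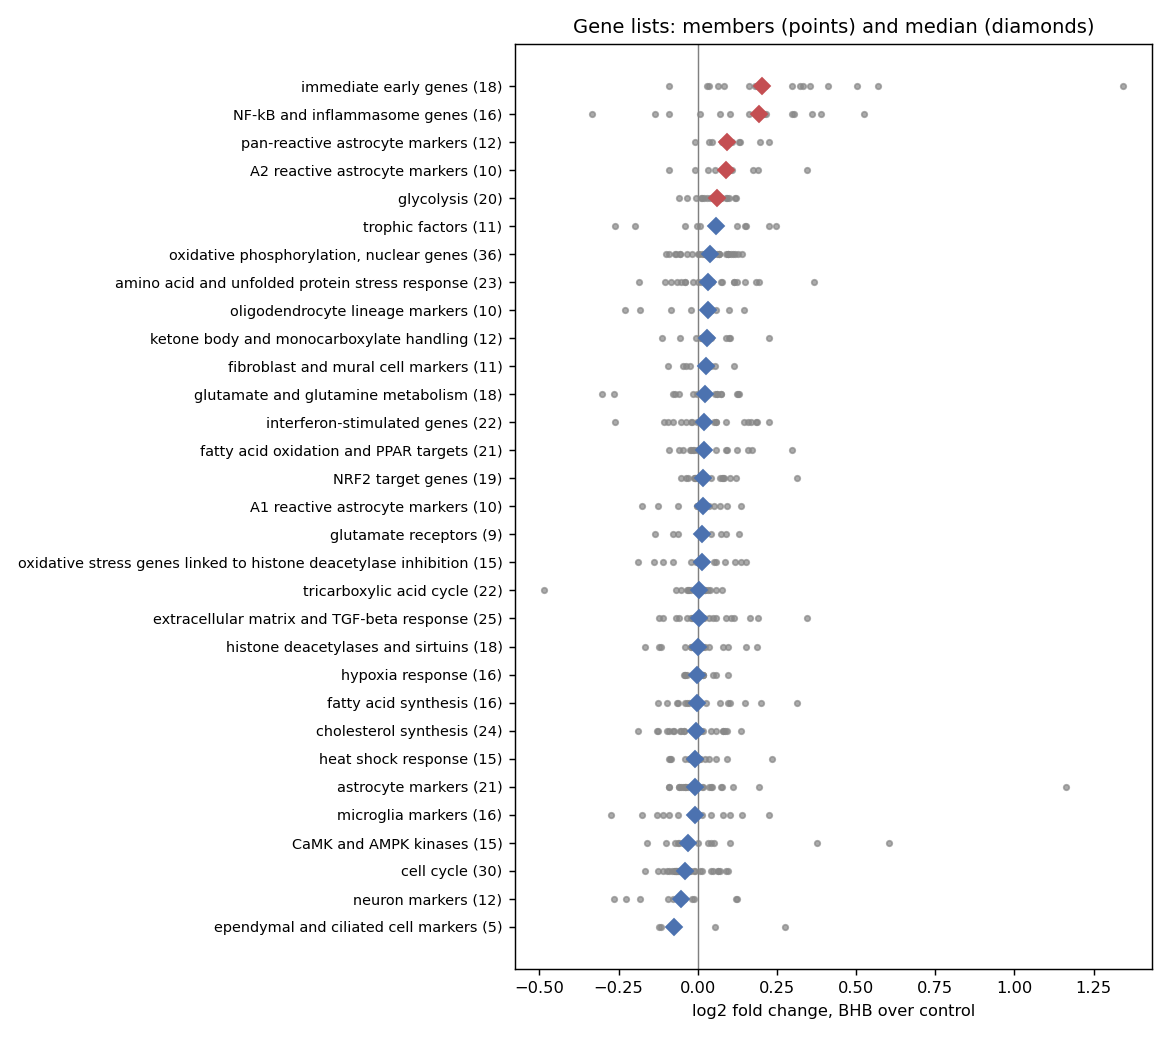
Log2 fold change (BHB over control) of the members of the 31 lists tested (grey points), with the median of each list as a diamond, red where camera with the preset correlation called the list and blue otherwise. Numbers of tested genes are in parentheses, and the medians of the 26 lists not called lie between -0.07 and 0.06.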

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

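The direction of the 7 genes that passed was the same under the alternatives run, with log2 fold changes of 1.13 to 1.18 for Slc1a3 and -0.48 to -0.44 for Epb41l2. Slc1a3 and Fosb passed in each alternative that tested them, at adjusted p of 2.01e-06 to 9.42e-04 and 7.32e-04 to 0.0263. Of 7 genes, 3 remained at an adjusted p under 0.01, 4 with at least a 1.5-fold and 2 with at least a 2-fold change on the log2(FPKM + 1) scale, as fewer genes meet a stricter threshold. Without the eBayes trend 4 were called, and the cause was not tested. Replicate numbers did not pair the libraries (correlations of deviations between same-numbered libraries -0.0899, 0.164 and -0.151). Control 3 correlated best with BHB 1 (0.203), control 1 with BHB 3 (0.186) and control 2 with BHB 2, a match in reverse order that no label gives and that was not used as a block. With the replicate block 2 genes were called, Slc1a3 and Fosb, with fewer residual degrees of freedom. Among genes with at most 6 decimals only, chosen after seeing the data, 2 were called, Fos and Fosb, since the other 5 were not tested. Leaving out a library gave 5 to 10 genes, and Slc1a3, Fosb and Igf1r passed each time. The log2 fold change of Slc1a1 ran from -0.0544 to 0.113, that of Slc16a7 ran from -0.0261 (without control 2) to 0.374 and that of Tagln from -0.00421 (without control 3) to 0.0638. Quantile normalization turned Acta2 to -0.0372 and Tagln to -0.0313, and the cause was not tested. Of the 5 lists called, 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.240. Fry called 2 (immediate early genes and astrocyte markers), and genes with at most 6 decimals gave 2 (immediate early and NF-kB genes). Leaving out a library gave 4 to 6 lists. Scaling the libraries to equal sums gave 5 lists higher and 2 lower, the cell cycle and neuron markers (adjusted p = 0.0488 each), and array weights called the cell cycle lower (0.0364). Of 674 other list values 641 stayed on their side of the threshold, 22 lost and 11 gained a call, and of 1329 values of named genes 1292 did, 33 lost a call and 4 turned. The lowest correlation between libraries was 0.990 in the main setting, 0.983 with a pseudocount of 0.1 and 0.994 without a filter, where genes near 0 weigh differently. Depth is unknown, and changes of 0.25 on the log2 scale were recovered in 18.4% of simulated genes, so small changes can be missed. The simulations held more changed genes than were called here, so this share may be too high for the data.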

Other observations

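Beyond the lists described above, growth and trophic factor genes had a single member higher adjusted over the list alone. Hbegf, an EGF receptor ligand, stood at 42.1 ± 1.19 FPKM in controls and 50.2 ± 1.91 FPKM with BHB (SD, n = 3 each), a log2 fold change of 0.25 that did not pass over all genes tested (limma adjusted p = 0.632). The list (11 tested, 7 above 0) was not called (camera adjusted p = 0.337). Cell cycle genes had 21 of 30 members below 0 and a median log2 fold change of -0.04 (camera adjusted p = 0.0930), with Top2a, a topoisomerase of dividing cells, at 73.8 and 68.4 FPKM. The list was called lower without control 3 (0.00465). Nuclear genes of oxidative phosphorylation had 28 of 36 above 0 and a median of 0.04 (camera adjusted p = 0.149), and were called higher without control 2 (3.22e-04) or without BHB 3 (0.00584). NRF2 targets (12 of 19 above 0) and fatty acid oxidation genes (13 of 21 above 0) were not called (camera adjusted p = 0.337 for each).

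The stress response to amino acid shortage and unfolded proteins (15 of 23 above 0, camera adjusted p = 0.409), cholesterol synthesis (11 of 24 above 0, 0.464), extracellular matrix (14 of 25 above 0, 0.649) and heat shock genes (7 of 15 above 0, 0.853) were not called, and the extracellular matrix list was called higher without BHB 1 (0.0494). The tricarboxylic acid cycle (12 of 22 above 0), interferon-stimulated genes (13 of 22), the hypoxia response (7 of 16) and fatty acid synthesis (7 of 16) were not called either, at a camera adjusted p of 0.938 for each. BHB 3 stood apart in the interferon-stimulated genes, with the highest value of 16 of the 22 members. Cxcl10 and Rsad2, named after their values were seen, were at 5.48 and 2.81 FPKM there, against at most 2.34 and 1.22 FPKM elsewhere. Without BHB 3 the interferon list was called lower with BHB (camera adjusted p = 1.64e-04), and it was called in 6 of the 9 other splits of the libraries into 3 and 3.

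The tests of explanations below were chosen after the values they bear on had been seen, including the definition of 2 tight levels, of which 4 versions were looked at. The 7 genes called compare with at most 4 in the other 9 splits of the 6 libraries into 3 and 3, while 3 of these 9 had more genes at an unadjusted p under 0.05 than the 692 of the real split, up to 1076. With 1 of 10 splits giving as many, the splits are too few for a share under 0.05. For lists, the real split called 5 and the highest other split 5, and 3 of 10 splits, the real one included, called as many. Immediate early genes were called in 4 of the other 9 splits and NF-kB genes in 2. Each of these 9 splits sets 2 libraries of a treatment with 1 of the other, so part of any treatment difference carries into it. Calls in these splits therefore do not measure chance alone.

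Slc1a3 at 2 tight levels that follow treatment is the pattern most in need of a second look. A scaling difference is argued against by the median log2 fold change of 0.00289 over the other genes tested (SD 0.121), and a larger share of astrocytes by -0.0199 over the other 20 astrocyte markers (SD 0.0725). Levels were first taken as each within 1.25-fold and at least 1.5-fold apart. Under this definition 100 of 6402 genes of at least 10 FPKM took 2 levels in groupings that did not follow treatment. Of these, 98 had more than 6 decimals, against 53.3% of the background genes (odds ratio 42.8, Fisher exact p = 4.04e-24). Shifts of isoform shares behind gene-level values could give this, and could apply to Slc1a3, whose values have more than 6 decimals. Igf1r, Coq10a, Prtfdc1 and Epb41l2 also have more than 6 decimals, as do 57.4% of the genes tested. Igf1r and Coq10a lie under 10 FPKM, and Prtfdc1 and Epb41l2 differ by less than 1.5-fold, so this definition leaves them out. Of the 100, 62 set 1 library apart, where that level is tight by definition, and 32 set 2 apart. The 9 other splits into 3 and 3 held 6 (mean 0.667 per split, highest 3), against 2 in the real split, Slc1a3 and Fos. The values of Fos have at most 6 decimals. Such levels thus occur in splits like that of Slc1a3 but were not frequent there under this first definition. With levels within 1.25-fold and at least 1.3-fold apart the real split held 4 (others mean 2.33, highest 5). With 1.1-fold and 1.5-fold it held 1 (0.111, 1), and with 1.1-fold and 1.3-fold 3 (0.444, 1). The real split lay above the mean of the other splits under the 4 definitions and above the highest under 1. Each of its counts includes Slc1a3, the gene in question, so it held at least 1 in advance. With 1.1-fold and 1.5-fold Slc1a3 was the only gene. This comparison is therefore no independent test, and neither this artifact nor an effect of BHB is excluded.

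Genes that show such levels, named after their values were seen, include Sparc and Cyb5r3. Sparc, whose values have at most 6 decimals, stood at 2936 FPKM in BHB 2 and 1441 to 1598 FPKM in the other libraries. Cyb5r3, whose values have more than 6, stood at 68.8 FPKM in control 1 and 131.4 to 156.5 FPKM in the others. Cdc42se2 stood at a mean of 7.78 FPKM in control 1, control 3 and BHB 1 and 17.5 FPKM in the rest, a ratio of 2.24 close to that of Slc1a3. Cdc42se2 was far less abundant than Slc1a3, and its lower level was looser, at 6.88 to 8.25 FPKM. Genes listed at 0 in a library were left out of that search, and 6 of at least 10 FPKM were. Outside the 100 genes, Potef is listed at 0 in BHB 3 and at 169.7 to 195.6 FPKM in the other libraries, and Aph1b at 0 in control 1 and control 3, 7.21 FPKM in control 2 and 7.89 to 8.75 FPKM with BHB. Of the 22 genes that were called only when a library was left out, counted once per library, 10 were among the 100 genes, as were 4 of the 18 called in the other splits into 3 and 3. Such overlap follows in part from the definition. Levels that set apart 2 libraries of a group separate the groups once its remaining library is left out.

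For the immediate early genes, 13 tested members have at most 6 decimals, a class with 2 of the 100 genes of 2 levels. Their median log2 fold change was 0.211 and 13 of 13 lay above 0, which argues against that artifact where the class holds few such genes. The search covered only genes of at least 10 FPKM. Members such as Fosb and Egr1 lie below that level, where the share of genes with 2 levels is unknown. A difference between libraries in handling or activation at harvest stays open, since 1 of 10 splits gave as large a mean difference (0.288, highest other 0.150), which is too few splits for a share under 0.05. The other splits keep part of any treatment difference, so 0.150 does not measure chance alone. Without Fos and Fosb the camera adjusted p was 3.04e-09 with the preset correlation, and the adjusted p was 0.359 with an estimated correlation (0.240 for the whole list).

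For the NF-kB and inflammasome genes, a larger share of microglia may be set against the microglia markers. Their median log2 fold change was -0.00974 (16 markers, 6 above 0), against 0.19 for the list, so the markers did not rise with the list. The SE of 0.0311 treats the markers as independent, though markers of the same cell type may vary together. A smaller rise in microglia is therefore not excluded. Whether the list moved through BHB or through chance differences between libraries cannot be settled with 10 splits.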
